A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

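The series used PCR-product arrays of the yeast genome hybridised with 2 labelled samples at once, 1 in Cy3 and 1 in Cy5. It held 14 arrays in 7 groups of 2. Each strain was hybridised against the reference strain yjdi363, with the strain in Cy5 on array 1 and in Cy3 on array 2. The groups were FHT-WT1 (whose label names the wild type), the construct strains DT1, TF1, HT4 and PB1, a strain labelled null, and a homotypic pair in which the reference was hybridised with itself. The labels do not explain the codes DT1, TF1, HT4 and PB1, and no domain is assigned to them here. The labels also do not say whether the 2 arrays of a group came from separate cultures. The p-values therefore measure only the spread between arrays, which may be technical.

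According to the labels, cells were grown in medium without leucine with 3% raffinose to an OD600 of 0.7, given 2% galactose for 30 min at 25 °C, and then held at 37 °C for 45 min. PolyA RNA was measured. The deposited values are log2 ratios of the 2 channels, for 7056 features on 14 arrays. According to the series text, the authors normalised the dye swap data by the mode in R and then corrected them with B. subtilis RNA added in proportion to culture density. These steps were checked on the values. Of the unnamed features, 425 reached a log2 ratio of 2 in size on at least 1 array, and 336 to 357 of these had a value on each array. Between 46.2% and 78.0% of those values lay within 0.00011 of the log2 of a ratio of whole numbers up to 12, against 3.68% to 5.31% when the values were shifted. An array-wide shift would have moved them off these ratios, so neither the mode normalisation nor the spike correction is visible as such a shift at these features. The mode of the named genes also differed between arrays, with 0.496 and -0.169 on null strain arrays 1 and 2 and 0.318 on homotypic array 1. The array medians are not read here as a spike-corrected RNA level.

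The direction of the ratios is not stated. Arrays of different strains in opposite dye orientation correlated with r between 0.137 and 0.703, as did the 2 arrays of each strain except FHT-WT1 (-0.0059), so the table was taken as already turned one way. TAF1 lay 10.4-fold from the reference in the null strain, and the ratios were taken as strain over reference on that basis. The homotypic arrays were used as deposited, with array 2 taken as turned like the other second arrays, which is not stated. Across genes the homotypic arrays correlated with strain arrays of the same number at a median r of 0.263 and with the others at -0.204. Homotypic array 1 correlated with array 1 of the strains at 0.2596 to 0.4049. Homotypic array 2 correlated with array 2 of FHT-WT1 at 0.272, but with array 2 of the other strains at -0.0309 to 0.0894. These values do not settle how homotypic array 2 was turned. Of the 7056 features, 5579 carry a gene name and 1477 do not. They give 5548 genes, of which 5543 matched the reference annotation (R64, used for names only) and 5 did not. Features of the same gene were averaged (30 genes, median SD 0.113). The 5535 genes with a value on all 14 arrays were tested, and 13 were left out. PCR products of near-identical paralogs, such as those of ribosomal proteins or SSA genes, can bind each other's transcripts.

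Changes were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), in 1 model with 7 groups and a term for dye orientation, with Benjamini-Hochberg adjustment over the 5535 genes and a threshold of 0.05, two-sided. The arrays were used as deposited. Because array medians differed, the number of called genes in each comparison is also given with each array centred on its median, as are counts of list members where centring moved them by over 1.5 times, and list medians are given on centred arrays. Gene lists were tested with camera in limma, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 190 tests. The lists were TFIID subunits, SAGA subunits, RNA polymerase II and general factors, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, heat shock chaperones, general stress genes, the galactose regulon, glycolysis and fermentation, histones, cyclins, amino acid biosynthesis, proteasome, respiratory chain, the mitochondrial genome, ergosterol biosynthesis, mating type a and alpha genes, and auxotrophic markers. None of the 8 mitochondrial-genome genes was measured. A comparison of promoters with and without a TATA box was planned and not run, because no genome sequence was used here.

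These choices, the comparisons, the lists and the rule for named genes were made before the data were examined. The rule took TAF1 first. For the null strain it took up to 10 called genes with the largest rise and up to 10 with the largest fall whose sign held in all 4 pairings of arrays, and for each other comparison up to 5 and 5. It added up to 4 members of each list by the size of the moderated statistic in the null strain comparison. The alternatives were centring or MAD scaling of the arrays, no orientation term, arrays of 2 groups alone, array weights, a 1.5-fold minimum, a robust prior, the homotypic arrays as control, each array left out in turn, fry, and camera with an estimated correlation. Alternatives added after seeing the data were unnamed features included, the same choices on centred arrays, and changes with FHT-WT1 not subtracted. Homotypic array 2 was also taken as not turned, a choice made beforehand.

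The fit was tested on simulated data, with 50 genes changed at each size between groups of 2 arrays. A change of 0.5 on the log2 scale was called in 6% of them as deposited and 52% after centring, a change of 1 in 92% under both, and changes of 1.5 and 2 in 100%. False calls numbered 12 and 9. A simulated list of 30 genes raised by 0.3 was called by camera in limma (Benjamini-Hochberg adjusted p = 8.64e-05), and 0 of 19 random lists were. The simulated noise was independent between genes, so this cannot show how often lists whose genes vary together are called falsely. Over the list tests of the real data the median estimated correlation was 0.633. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9, and tables were prepared with pandas 2.3.3 and numpy 2.4.6. Each group had 2 arrays, which limits the precision.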

Results

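The data were log2 ratios of polyA RNA in strain over reference for 5535 yeast genes on 14 arrays, with 2 arrays of opposite dye orientation for each of 7 groups. The title asks which genes depend on which functional domains of TAF1, the largest subunit of the general transcription factor TFIID. In the strains, TAF1 constructs were induced with galactose before a shift to 37 °C. FHT-WT1, whose label names the wild type, was the control for DT1, TF1, HT4, PB1 and the null strain. The arrays held 6935 to 6971 features with a value each. Unless another error is named, changes are log2 differences between groups ± SE from limma, with n = 2 arrays per group. As deposited, limma drew the spread of each gene largely to a value shared by all genes (87.9 prior against 6 residual degrees of freedom). The median SE was 0.2345, and an SE as deposited says little about the arrays of a single gene. After centring the prior had 6 degrees of freedom. The largest rises and falls are those among called genes whose sign was the same in all 4 pairings of 1 array of each group.

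TAF1 RNA separated the null strain from the other strains. Its log2 ratio to the reference was -3.37 ± 0.38 (SD, n = 2) in the null strain, 10.4-fold below the reference, and -0.29 ± 0.42 in FHT-WT1. In DT1, TF1, HT4 and PB1 it was -0.65 ± 0.34, -0.40 ± 0.65, -0.82 ± 0.53 and -0.42 ± 0.28, and in the homotypic pair 0.30 ± 0.17. Against FHT-WT1, TAF1 fell by 3.08 ± 0.24 in the null strain, an 8.47-fold difference (limma, Benjamini-Hochberg adjusted p = 1.26e-18). The direction of this fall is assumed and is not a result, because the ratios were taken as strain over reference from TAF1 in the null strain. Every higher or lower value in these results rests on the same choice. TAF1 RNA was higher than in the null strain by 2.73, 2.97, 2.56 and 2.96 in DT1, TF1, HT4 and PB1, and each of these was called (limma, Benjamini-Hochberg adjusted p of at most 2.15e-14). It was not called against FHT-WT1 in these 4 strains (limma, Benjamini-Hochberg adjusted p = 0.619, 0.997, 0.182 and 0.926), and its sign in TF1 and PB1 turned to 0.043 and 0.053 when arrays were scaled by their spread. The arrays measure RNA, and the level of TAF1 protein was not analysed here.

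**Figure D1:**
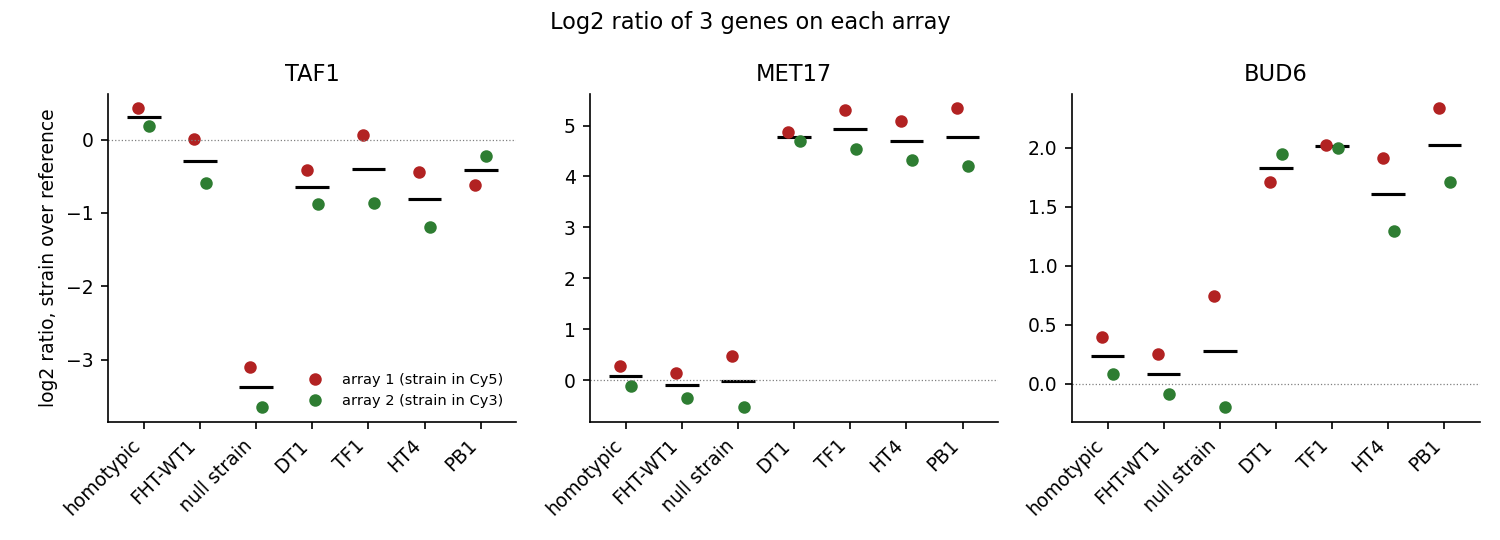
Log2 ratio of strain over reference of TAF1, MET17 and BUD6 on each array (points, coloured by dye orientation) and its mean over 2 arrays (lines) in the 7 groups, where the homotypic arrays hold the reference in both channels. TAF1 was lowest on the null strain arrays, and MET17 was highest on the arrays of DT1, TF1, HT4 and PB1.

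The median log2 ratio of all genes differed between arrays, most within the null strain pair (0.412 and -0.184). The group means were 0.055 ± 0.018 (SD, n = 2) in FHT-WT1, -0.105 ± 0.004 in DT1, 0.084 ± 0.174 in TF1, -0.15 ± 0.03 in HT4, 0.121 ± 0.126 in PB1, 0.114 ± 0.421 in the null strain and 0.273 ± 0.04 in the homotypic pair. Whether homotypic array 2 was turned like the other second arrays is not stated, and with its sign reversed the homotypic mean was 0.029. No global rise or fall of RNA is read from these medians, because no spike correction is visible in the values. Relative to FHT-WT1, the median gene lay at -0.17 in DT1, 0.02 in TF1, -0.21 in HT4, 0.06 in PB1 and 0.05 in the null strain, so counts of higher and lower genes are given as deposited and with arrays centred. Across genes, which are not independent replicates, the 2 arrays of a strain correlated with r between 0.509 and 0.662 in the other strains, while those of FHT-WT1, the control, correlated with -0.0059 (median of the 6 strains 0.627). Arrays of different strains in the same dye orientation correlated with a median r of 0.694, and those in opposite orientation with 0.506.

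The null strain, where TAF1 RNA was lowest, was set against FHT-WT1. Genes for nitrogen uptake were the largest rises: MEP2, an ammonium permease, rose by 1.497 ± 0.263 and DUR3, a urea transporter, by 1.42 ± 0.26 (limma, Benjamini-Hochberg adjusted p = 0.000401 and 0.000492). Both also rose in DT1, TF1, HT4 and PB1, by 1.501 and 1.276 in DT1 and by 1.765 and 1.417 in TF1. TAF1 RNA was not called against FHT-WT1 in those strains, so these rises did not follow TAF1 RNA. Other called genes included the aconitase gene ACO1 (1.17 ± 0.24), the glutamate dehydrogenase gene GDH1 (1.13 ± 0.25), the glycerol metabolism genes GPD1 (1.08 ± 0.24) and GUT2 (1.08 ± 0.24), FET5 (1.23 ± 0.25), HRP1 (1.13 ± 0.24), BDH2 (1.08 ± 0.24) and ACH1 (1.06 ± 0.24). The rise of FET5 owed much of its size to FHT-WT1 array 1, where it lay at -1.41, against -0.31 on FHT-WT1 array 2. Besides TAF1, the largest falls were MF(ALPHA)1, which encodes the alpha-factor pheromone (-1.27 ± 0.25), DFP4 (-1.10 ± 0.24), RNH203, a subunit of ribonuclease H2 (-1.001 ± 0.236), ADI1 of methionine salvage (-0.93 ± 0.24) and ECM15 (-0.91 ± 0.23). MF(ALPHA)1 lay at -0.12 on FHT-WT1 array 1 and at -1.39 on FHT-WT1 array 2. The size of its fall in each strain set against FHT-WT1 thus depends on the control array. PUS5 (-1.07 ± 0.27) was also called, but its sign did not hold in all pairings, with 2.04 on FHT-WT1 array 2 and -0.125 on FHT-WT1 array 1. In all, 38 genes were called as deposited, 31 higher and 7 lower (524 at an unadjusted p under 0.05). After centring, 333 were called, 105 higher and 228 lower, of which 28 were called both ways. The count was 16 without FHT-WT1 array 1, 17 without FHT-WT1 array 2, 877 without null strain array 1 and 302 without null strain array 2. After centring it was 38, 42, 709 and 1 without the same arrays, 189 without either DT1 array and 112 without either TF1 array. Of the genes that met the rule on signs, TAF1 and DUR3 kept their call as deposited whichever array was left out. MEP2 lost it without null strain array 1, and the others lost it without 1 or both FHT-WT1 arrays, with DFP4, RNH203, ADI1, ECM15 and ACH1 also losing it without null strain array 2, and ECM15 without either homotypic array. ACH1 was not called after centring.

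Among the fixed lists, cytosolic ribosomal protein genes lay lower and metabolic and stress genes higher in the null strain than in FHT-WT1, relative to all genes. The median of the 135 ribosomal protein genes was -0.44, with 132 below the median of all genes (camera in limma, Benjamini-Hochberg adjusted p = 1.9e-28; adjusted p = 0.904 with an estimated correlation). None of the 135 was called as deposited by limma, over all genes or adjusted over the list alone, and 36 fell after centring (88 adjusted over the list alone), among them RPL27A (-0.71 ± 0.24 as deposited). The 26 general stress genes had a median of 0.54 (camera, Benjamini-Hochberg adjusted p = 7.42e-11; adjusted p = 0.592 with an estimated correlation), and 1 of them, GPD1, rose (15 adjusted over the list alone; 7 rose after centring). Glycolysis and fermentation genes had a median of 0.33 (camera, Benjamini-Hochberg adjusted p = 7.39e-06; adjusted p = 0.683 with an estimated correlation), with 0 of 16 called by limma as deposited, 2 adjusted over the list alone and 1 after centring. Amino acid biosynthesis genes had a median of 0.22 (camera, Benjamini-Hochberg adjusted p = 2.51e-06; adjusted p = 0.989 with an estimated correlation). Of these 37 genes 2 rose, the arginine synthesis genes ARG1 (0.98 ± 0.23) and ARG3 (0.96 ± 0.24), with 4 adjusted over the list alone and 6 after centring. The 31 respiratory chain genes had a median of 0.16 (camera, Benjamini-Hochberg adjusted p = 2.73e-05; adjusted p = 0.989 with an estimated correlation), and SDH1 (1.01 ± 0.24) and ATP1 (0.95 ± 0.24) rose (7 adjusted over the list alone, 1 member after centring). The 4 alpha-specific mating genes had a median of -0.78 (camera, Benjamini-Hochberg adjusted p = 1.38e-07; adjusted p = 0.417 with an estimated correlation), and 1 of them, MF(ALPHA)1, fell (3 adjusted over the list alone, 2 after centring). Histone genes had a median of 0.26 (camera, Benjamini-Hochberg adjusted p = 0.0488; adjusted p = 0.989 with an estimated correlation). The 24 heat shock chaperone genes were not called as a list (median 0.11, camera, Benjamini-Hochberg adjusted p = 0.522), although SSA4, a stress-induced Hsp70, rose by 0.91 ± 0.24. The calls of ARG1, ARG3, SDH1, ATP1, SSA4 and GPD1 were each lost without 1 or the other FHT-WT1 array, and SDH1, ATP1 and SSA4 were not called after centring. TFIID subunits had a median of -0.09 and were not called as a list (camera, Benjamini-Hochberg adjusted p = 0.078).

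FHT-WT1 was set against the homotypic pair to show how far the wild type construct strain lay from the reference. No gene was called by limma as deposited or after centring, with 346 and 275 genes at an unadjusted p under 0.05. Without FHT-WT1 array 1 there were 15 called and without array 2 there were 10, with 5 without any 1 array of DT1, TF1 or HT4, and 2 and 4 without homotypic array 1 or 2. After centring 6 and 8 were called without FHT-WT1 array 1 or 2, and 4 without homotypic array 2. Ribosomal protein genes had a median of -0.23, with 129 of 135 below all genes (camera in limma, Benjamini-Hochberg adjusted p = 1.12e-23; adjusted p = 0.95 with an estimated correlation). Ribosome biogenesis genes had a median of -0.24, with 30 of 32 below (camera, Benjamini-Hochberg adjusted p = 6.4e-11; adjusted p = 0.95 with an estimated correlation). The alpha-specific genes had a median of -0.53 (camera, Benjamini-Hochberg adjusted p = 3.36e-09; adjusted p = 0.417 with an estimated correlation), with 4 of 4 called as deposited when adjusted over the list alone and 0 after centring. Smaller medians were called for heat shock chaperones (0.12), general stress genes (0.13), amino acid biosynthesis (0.08) and ergosterol biosynthesis (-0.14), with camera and Benjamini-Hochberg adjusted p between 0.000426 and 0.00823, and adjusted p = 0.989 with an estimated correlation for each. The heat shock list was not called after centring. With the sign of homotypic array 2 reversed, the ribosomal protein, ribosome biogenesis, alpha-specific and ergosterol lists stayed lower (camera, Benjamini-Hochberg adjusted p = 7.15e-15, 0.032, 0.000353 and 0.0444). Heat shock and general stress genes then turned lower (camera, Benjamini-Hochberg adjusted p = 0.019 and 0.0023), and amino acid biosynthesis was not called (adjusted p = 0.936). Respiratory chain and glycolysis genes, not called before, were then lower (camera, Benjamini-Hochberg adjusted p = 1.4e-09 and 6.94e-06). An estimated correlation was not tried with this sign.

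**Figure D2:**
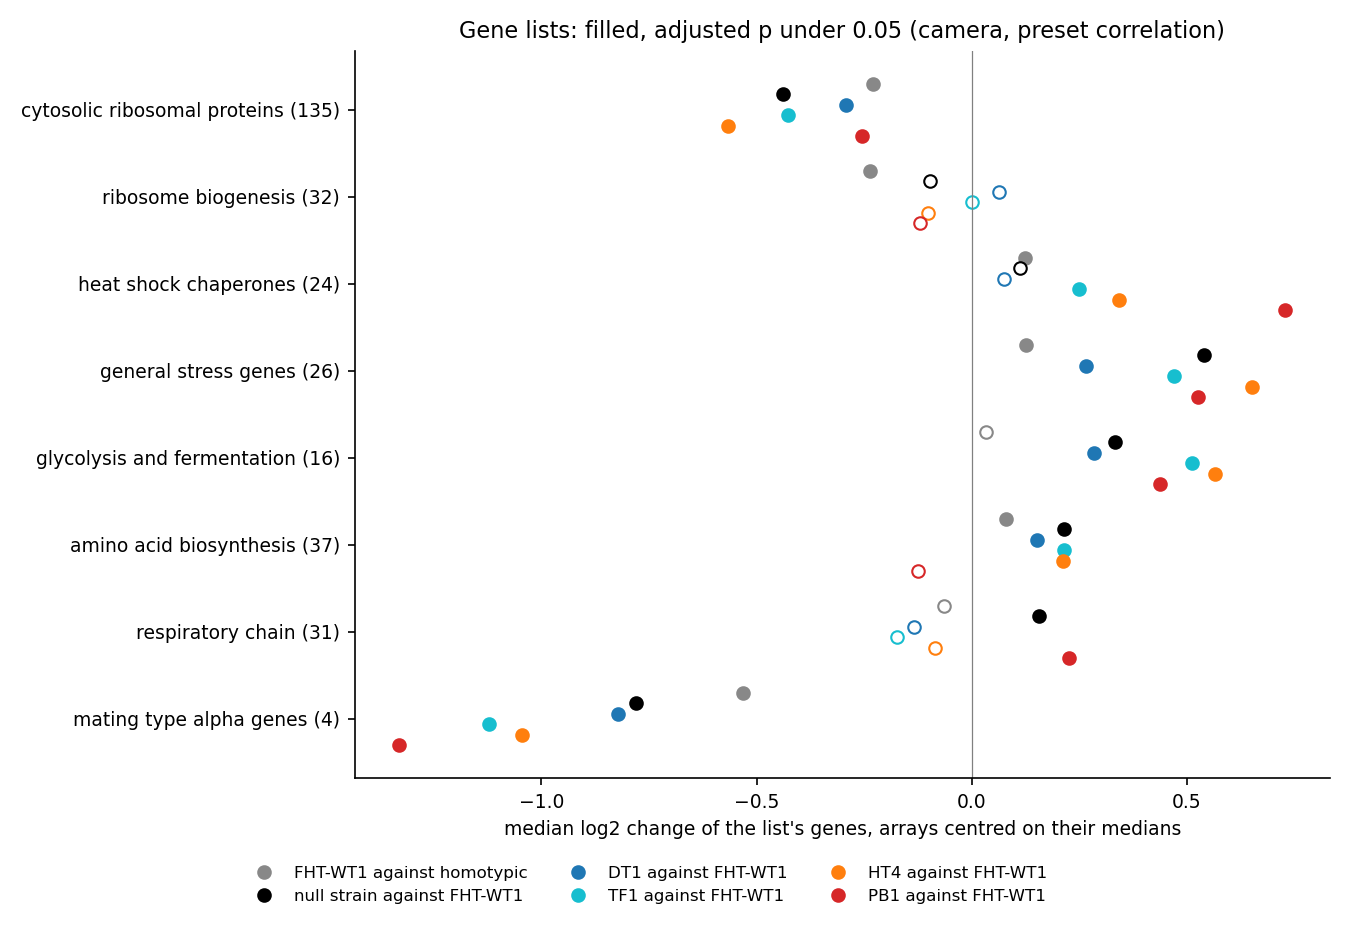
Median log2 change of the genes of 8 fixed lists in each comparison, on arrays centred on their medians, with list sizes in brackets. Filled points mark an adjusted p under 0.05 from camera on values as deposited with the preset correlation, and no list passed with an estimated correlation; ribosomal protein genes lay below 0 in all 6 comparisons.

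DT1 differed from FHT-WT1 most at MET17, which encodes a sulfur assimilation enzyme and is a common auxotrophic marker. MET17 rose by 4.89 ± 0.24, a 29.6-fold difference, and BUD6, a cell polarity gene, by 1.75 ± 0.24 (limma, Benjamini-Hochberg adjusted p = 4.63e-33 and 2.33e-07). MEP2 rose by 1.501 ± 0.263 and DUR3 by 1.28 ± 0.26, while MF(ALPHA)1 (-1.27 ± 0.25), STE3, the a-factor receptor gene (-1.11 ± 0.24), NTO1 (-1.21 ± 0.24) and DFP4 (-1.16 ± 0.24) fell. The fall of NTO1 owed much of its size to FHT-WT1 array 1, where it lay at 1.17, against -0.049 on FHT-WT1 array 2. YIL055C (1.59 ± 0.28), PUS5 (-1.47 ± 0.27) and AIM19 (-1.40 ± 0.29) were also called, but were not called after centring, nor were MF(ALPHA)1, STE3 and NTO1. In all, 49 genes were called, 8 higher and 41 lower (627 at an unadjusted p under 0.05). After centring there were 50, 11 higher and 39 lower, with 31 called both ways. The count was 30 and 11 without FHT-WT1 array 1 or 2, 12 and 11 without DT1 array 1 or 2, 32 without any 1 array of TF1 or the homotypic pair, and 367 without either null strain array. After centring it ranged from 1 without DT1 array 2 to 80 without either null strain array, with 11 without DT1 array 1, 24 without either TF1 array, 27 without FHT-WT1 array 2 and 78 without either PB1 array. MET17, BUD6 and MEP2 kept their call as deposited whichever array was left out. DUR3, PUS5 and AIM19 lost it without FHT-WT1 array 2, YIL055C without DT1 array 2, and the others without at least 1 array of DT1.

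Ribosomal protein genes had a median of -0.29 in DT1, with 127 of 135 below all genes (camera in limma, Benjamini-Hochberg adjusted p = 4.22e-14; adjusted p = 0.989 with an estimated correlation). None of them was called by limma as deposited or after centring, and 18 were after centring when adjusted over the list alone. General stress genes had a median of 0.27 and glycolysis genes 0.28 (camera, Benjamini-Hochberg adjusted p = 4.72e-05 and 1.12e-05). These lists gave adjusted p = 0.959 and adjusted p = 0.695 with an estimated correlation, and limma called no member over all genes as deposited (0 higher and 1 lower stress gene adjusted over the list alone). Amino acid biosynthesis genes had a median of 0.15 (camera, Benjamini-Hochberg adjusted p = 6.34e-06, and adjusted p = 0.989 with an estimated correlation), and MET17 was the 1 member that rose. Of the 37 genes 29 lay above the median of all genes, and the list was not tested without MET17. Of the 4 alpha-specific genes, 3 fell (4 adjusted over the list alone, 0 after centring), with a median of -0.82 (camera, Benjamini-Hochberg adjusted p = 6.76e-09; adjusted p = 0.417 with an estimated correlation).

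MET17 and BUD6 were also the largest rises in TF1. MET17 rose by 5.03 ± 0.24 (32.7-fold), BUD6 by 1.93 ± 0.24, MEP2 by 1.77 ± 0.26, DUR3 by 1.42 ± 0.26 and SPS100, a spore wall gene, by 1.30 ± 0.25 (limma, Benjamini-Hochberg adjusted p = 4.99e-34, 5.75e-09, 2.01e-06, 0.000262 and 0.000591). The largest falls were MF(ALPHA)1 (-2.00 ± 0.25), the S-phase cyclin gene CLB6 (-1.67 ± 0.33), STE3 (-1.39 ± 0.24), PUS5 (-1.29 ± 0.27) and AFB1 (-1.21 ± 0.23). CLB6 and PUS5 were not called after centring, and CLB6 was not called without TF1 array 1. As deposited 29 genes were called, 15 higher and 14 lower (419 at an unadjusted p under 0.05). After centring there were 206, 61 higher and 145 lower, with 26 called both ways. The count was 17 without FHT-WT1 array 1, 10 without TF1 array 1 and 140 without either null strain array. After centring it was 25 and 71 without FHT-WT1 array 1 or 2, 3 and 15 without TF1 array 1 or 2, and 111 without either DT1 array. MET17, BUD6, MEP2 and MF(ALPHA)1 kept their call as deposited whichever array was left out, while DUR3 lost it without TF1 array 1, SPS100 without TF1 array 2, PUS5 without FHT-WT1 array 2 or TF1 array 2, and STE3 and AFB1 without FHT-WT1 array 1.

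The median of the ribosomal protein genes in TF1 was -0.43, with 133 of 135 below all genes (camera in limma, Benjamini-Hochberg adjusted p = 8.87e-30; adjusted p = 0.879 with an estimated correlation). None was called by limma as deposited, and 24 fell after centring (91 adjusted over the list alone). Glycolysis genes had a median of 0.51 (camera, Benjamini-Hochberg adjusted p = 5.24e-12; adjusted p = 0.417 with an estimated correlation), with 14 of 16 higher when adjusted over the list alone and 0 over all genes (4 after centring). General stress genes had a median of 0.47 (camera, Benjamini-Hochberg adjusted p = 1.11e-10; adjusted p = 0.592 with an estimated correlation), with 9 of 26 higher when adjusted over the list alone and 0 over all genes (4 after centring). Heat shock chaperones had a median of 0.25 and amino acid biosynthesis 0.21 (camera, Benjamini-Hochberg adjusted p = 2e-04 and 2.24e-07), with adjusted p = 0.959 and adjusted p = 0.974 with an estimated correlation. MET17 is in the amino acid list and was its 1 called member as deposited and after centring. Of the 37 genes 30 lay above the median of all genes, and the list was not tested without MET17. Of the alpha-specific genes, 2 fell (4 adjusted over the list alone, 3 after centring), with a median of -1.12 (camera, Benjamini-Hochberg adjusted p = 7.06e-15; adjusted p = 0.312 with an estimated correlation).

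HT4 had the most called genes of the strains set against FHT-WT1 as deposited and after centring, with all arrays used. As deposited, this ranking was lost without HT4 array 1. HT4 then had 1 array beside 2 in the other strains, so the counts cannot show whether the ranking rested on that array or fell with the number of arrays. The highest were MET17 (4.81 ± 0.24, 28.0-fold), BUD6 (1.52 ± 0.24), MEP2 (1.43 ± 0.26), SPS100 (1.40 ± 0.25) and DUR3 (1.31 ± 0.26). The lowest were MF(ALPHA)1 (-1.80 ± 0.25), STE3 (-1.68 ± 0.24), ECM15 (-1.64 ± 0.23), PUS5 (-1.51 ± 0.27) and GRH1, a Golgi gene (-1.43 ± 0.24). Each of these 10 was called by limma with a Benjamini-Hochberg adjusted p of at most 0.000512, and PUS5 was not called after centring. Ribosomal protein genes fell in number: 74 of 135 were called lower as deposited (120 adjusted over the list alone) and 83 after centring (116 adjusted over the list alone). These counts were 0 and 15 without HT4 array 1, 36 and 44 without HT4 array 2, 7 and 23 without FHT-WT1 array 1, 8 and 51 without FHT-WT1 array 2, and 119 and 94 without either null strain array. Examples were RPS17B (-1.11 ± 0.25), RPS10B (-0.98 ± 0.25) and RPL27A (-0.97 ± 0.24), whose calls were lost without HT4 array 1. Their median was -0.57, with 133 of 135 below all genes (camera in limma, Benjamini-Hochberg adjusted p = 1.49e-33; adjusted p = 0.778 with an estimated correlation). In all, 341 genes were called, 39 higher and 302 lower (1172 at an unadjusted p under 0.05). After centring there were 648, 271 higher and 377 lower, with 301 called both ways. The share of lower genes was 88.6% as deposited and 58.2% after centring, so it moved with the array medians. The count was 86 and 65 without FHT-WT1 array 1 or 2, 36 and 127 without HT4 array 1 or 2, and 1200 without either null strain array. After centring it was 235 and 363 without FHT-WT1 array 1 or 2, and 159 and 311 without HT4 array 1 or 2. PUS5 and GRH1 lost their call without FHT-WT1 array 2.

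Stress and glycolytic genes lay higher in HT4. General stress genes had a median of 0.65 (camera in limma, Benjamini-Hochberg adjusted p = 1.83e-14; adjusted p = 0.516 with an estimated correlation), and 2 of 26 rose as deposited and 16 after centring (9 and 19 adjusted over the list alone). One of them was GPD1 (0.76 ± 0.24), whose call was lost without an array of FHT-WT1, DT1, TF1, HT4 or the homotypic pair. Glycolysis genes had a median of 0.57 (camera, Benjamini-Hochberg adjusted p = 3.24e-10; adjusted p = 0.441 with an estimated correlation), with 0 called by limma as deposited and 7 of 16 higher after centring (0 and 14 adjusted over the list alone). Heat shock chaperones had a median of 0.34 (camera, Benjamini-Hochberg adjusted p = 5.89e-07; adjusted p = 0.778 with an estimated correlation), and 2 rose and 1 fell as deposited, and 1 rose and 0 fell after centring. Amino acid biosynthesis had a median of 0.21 (camera, Benjamini-Hochberg adjusted p = 0.000167, and adjusted p = 0.989 with an estimated correlation). MET17 was the 1 member of this list that rose as deposited (4 rose after centring). Of the 37 genes 27 lay above the median of all genes, and the list was not tested without MET17. Histones had a median of 0.23 and proteasome genes -0.17 (camera, Benjamini-Hochberg adjusted p = 0.0486 and 0.0362; adjusted p = 0.989 with an estimated correlation for each). Of the alpha-specific genes 3 fell (4 adjusted over the list alone, 2 after centring), with a median of -1.04 (camera, Benjamini-Hochberg adjusted p = 2.26e-07; adjusted p = 0.417 with an estimated correlation).

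PB1 was marked by heat shock genes. BTN2, a heat-induced protein sorting factor, rose by 1.96 ± 0.26 (3.88-fold) and SSA4 by 1.51 ± 0.24 (2.84-fold), beside HSP30 (1.34 ± 0.25) and the mitochondrial chaperone gene HSP78 (1.24 ± 0.24; limma, Benjamini-Hochberg adjusted p = 2.69e-08, 6.73e-06, 3e-04 and 0.000371). Of 24 heat shock chaperone genes, 10 rose as deposited (16 adjusted over the list alone) and 6 after centring (14 adjusted over the list alone), with a median of 0.73 (camera in limma, Benjamini-Hochberg adjusted p = 3.37e-16; adjusted p = 0.417 with an estimated correlation). MET17 (4.88 ± 0.24, 29.4-fold), BUD6 (1.94 ± 0.24) and GTA1 (1.58 ± 0.35) also rose. The largest falls were MF(ALPHA)1 (-2.05 ± 0.25), YIL014C-A (-1.71 ± 0.23), STE3 (-1.53 ± 0.24), EMA35 (-1.40 ± 0.23) and the alcohol dehydrogenase gene ADH7 (-1.33 ± 0.23). In all, 107 genes were called, 72 higher and 35 lower (589 at an unadjusted p under 0.05). After centring there were 407, 150 higher and 257 lower, with 87 called both ways. The share of lower genes was 32.7% as deposited and 63.1% after centring, so which direction had more genes depended on the array medians. The count was 36 and 59 without FHT-WT1 array 1 or 2, 45 without PB1 array 2 and 359 without either null strain array. After centring it was 103 and 236 without FHT-WT1 array 1 or 2, 169 and 173 without PB1 array 1 or 2, and 251 without either TF1 array. GTA1 was not called after centring or without PB1 array 2 or either null strain array, and HSP78 and HSP30 were not called without FHT-WT1 array 1.

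Stress, glycolytic and respiratory genes also lay higher in PB1 than all genes. General stress genes had a median of 0.53 (camera in limma, Benjamini-Hochberg adjusted p = 1.91e-12; adjusted p = 0.564 with an estimated correlation), and 5 of 26 rose as deposited (14 adjusted over the list alone, 10 after centring). Glycolysis genes had a median of 0.44 (camera, Benjamini-Hochberg adjusted p = 2.01e-07; adjusted p = 0.564 with an estimated correlation), and 1 of 16 rose (7 adjusted over the list alone, 4 after centring). The respiratory chain had a median of 0.23 (camera, Benjamini-Hochberg adjusted p = 5.11e-05; adjusted p = 0.989 with an estimated correlation), with SDH1 (0.86 ± 0.24) and ATP1 (0.84 ± 0.24) called as deposited and not after centring or without an array of FHT-WT1 or PB1. Ribosomal protein genes had a median of -0.26, with 122 of 135 below all genes (camera, Benjamini-Hochberg adjusted p = 5.94e-09; adjusted p = 0.989 with an estimated correlation), 0 called by limma as deposited and 9 after centring. Histones (0.38) and cyclins (0.22) were called as lists (camera, Benjamini-Hochberg adjusted p = 0.0134 and 0.0419; adjusted p = 0.989 with an estimated correlation for each). All 4 alpha-specific genes fell as deposited and after centring, with a median of -1.33 (camera, Benjamini-Hochberg adjusted p = 2.19e-16; adjusted p = 0.312 with an estimated correlation). Amino acid biosynthesis genes had a median of -0.13 and were not called (camera, Benjamini-Hochberg adjusted p = 0.89).

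**Figure D3:**
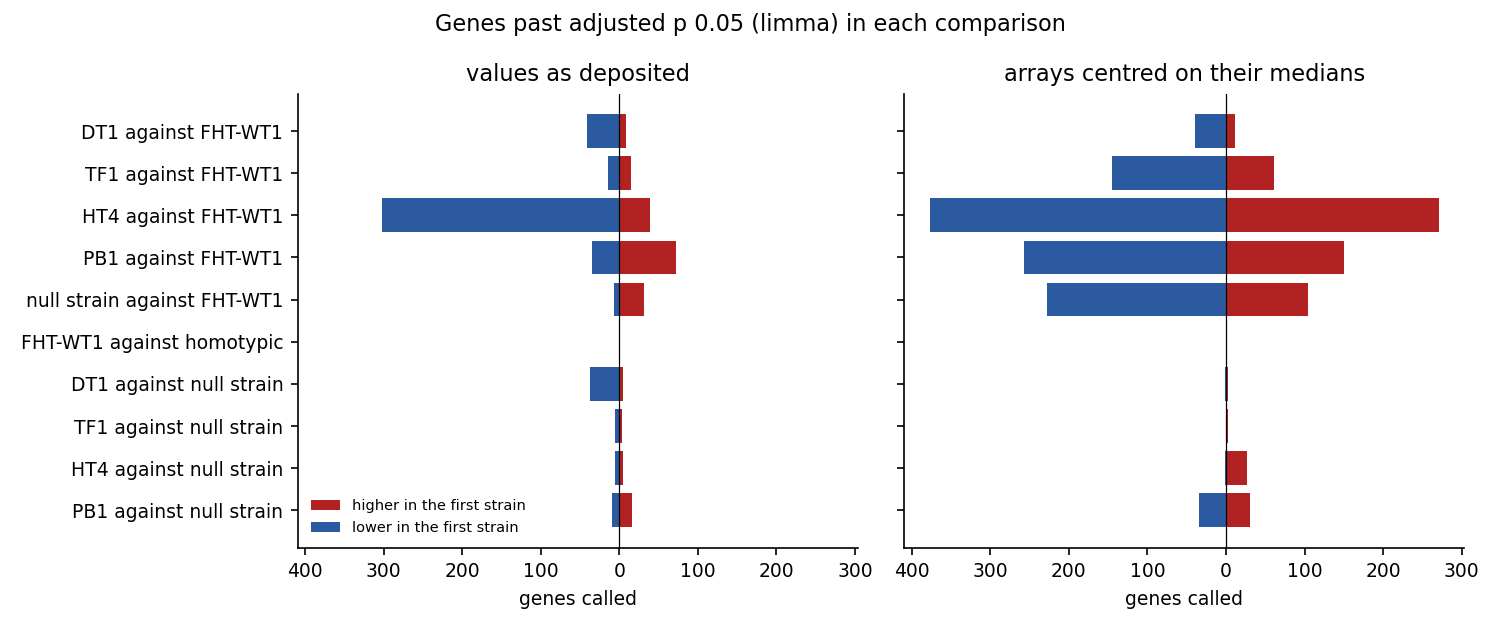
Number of genes called higher and lower in each comparison by limma with a Benjamini-Hochberg adjusted p under 0.05, as deposited and with arrays centred. With all arrays used, HT4 had the most calls against FHT-WT1 (341 as deposited and 648 centred), and FHT-WT1 against the homotypic pair had 0.

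Whether a construct strain differed from the null strain was tested directly. Besides TAF1, MET17 (4.80, 4.94, 4.72 and 4.79 in DT1, TF1, HT4 and PB1) and BUD6 (1.55, 1.74, 1.33 and 1.75) were higher in all 4 construct strains, with an SE of 0.24 for each value, and were called as deposited and after centring. BUD6 lost its call as deposited in DT1 without DT1 array 2 and in HT4 without HT4 array 1. FHT-WT1 and the null strain lacked the rise of both genes, so the 4 construct strains share a difference from both that does not follow TAF1 RNA. PB1 lay above the null strain at BTN2 (1.40 ± 0.26) and TDA6 (1.28 ± 0.24), and below it at YCR101C (-1.43 ± 0.23), EMA35 (-1.17 ± 0.23), YIL014C-A (-1.16 ± 0.23), AGA1, an anchor of a cell adhesion protein (-1.16 ± 0.23), and the arginine gene ARG4 (-1.03 ± 0.24; limma, Benjamini-Hochberg adjusted p of at most 0.0139). Of these, BTN2 was not called after centring, and YCR101C alone kept its call without PB1 array 1. DT1 lay below the null strain at PAL1 (-1.89 ± 0.32), YIR042C (-1.50 ± 0.25), ERP1 (-1.37 ± 0.25), the lactate permease gene JEN1 (-1.25 ± 0.24), MSS4 (-1.25 ± 0.24) and the galactose permease gene GAL2 (-1.11 ± 0.23), of which YIR042C alone was called after centring, and alone kept its call as deposited whichever array was left out. Falls called in TF1 (PAL1 -1.61, GTA1 -1.49, CLB6 -1.47, MDM31 -1.13 and YHB1 -1.01) and in HT4 (KAP104 -1.27, YHB1 -1.07, PHO89 -1.05, JEN1 -1.05 and SSB1 -1.03) were not called after centring, and each was lost without at least 1 array of the strain or the null strain.

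The number of genes called against the null strain was 41 in DT1 (4 higher and 37 lower), 9 in TF1 (3 and 6), 10 in HT4 (4 and 6) and 26 in PB1 (16 and 10), with 580, 125, 765 and 285 at an unadjusted p under 0.05 by limma. After centring it was 4 (3 and 1), 3 (3 and 0), 28 (27 and 1) and 65 (30 and 35). Without null strain array 1 the counts were 95, 258, 56 and 583, and without null strain array 2 they were 2905, 4, 3693 and 144. After centring they were 146, 53 and 62 in DT1, TF1 and HT4 without null strain array 1, and 2, 2 and 15 in DT1, HT4 and PB1 without null strain array 2. DT1 then gave 8 and 2 without its array 1 or 2, TF1 13 without its array 2, PB1 23 without its array 1, and HT4 12 to 18 without any 1 array of FHT-WT1, DT1, TF1, HT4 or the homotypic pair. As deposited, DT1 gave 12 and 10 without its own array 1 or 2 and 26 without any 1 array of TF1 or the homotypic pair, HT4 gave 16 without either PB1 array, and PB1 gave 13 without its array 1.

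Lists also differed between the construct strains and the null strain. Heat shock chaperones lay higher in PB1 (median 0.60, camera in limma, Benjamini-Hochberg adjusted p = 1.72e-21; adjusted p = 0.417 with an estimated correlation), with 2 of 24 rising (16 adjusted over the list alone, 0 after centring). They also lay higher in HT4 (0.27) and TF1 (0.16), with camera and Benjamini-Hochberg adjusted p = 4.54e-10 and 5e-05, and adjusted p = 0.564 and adjusted p = 0.95 with an estimated correlation. Amino acid biosynthesis genes lay lower in PB1 than in the null strain, with 36 of 37 below all genes (median -0.40, camera, Benjamini-Hochberg adjusted p = 1.02e-08; adjusted p = 0.95 with an estimated correlation). Respiratory chain genes lay lower in DT1 (-0.34), TF1 (-0.38, 31 of 31 below) and HT4 (-0.23), with camera and Benjamini-Hochberg adjusted p = 7.06e-15, 6.08e-20 and 4.97e-08; with an estimated correlation these were adjusted p = 0.625, adjusted p = 0.561 and adjusted p = 0.95. Of the 31 genes, 3 fell in DT1 as deposited (24 adjusted over the list alone), including SDH1 (-1.004 ± 0.241) and SDH4 (-0.96 ± 0.24), whose calls were lost without either DT1 array, and 0 after centring (1 adjusted over the list alone). Ribosomal protein genes lay higher than in the null strain in DT1 (0.15) and PB1 (0.17) and lower in HT4 (-0.11), with camera and Benjamini-Hochberg adjusted p = 1.12e-07, 2.66e-07 and 0.000625, and adjusted p = 0.989 with an estimated correlation for each. The alpha-specific genes lay lower in PB1 (-0.60) and TF1 (-0.34), with camera and Benjamini-Hochberg adjusted p = 7.67e-06 and 0.000592, and adjusted p = 0.441 and adjusted p = 0.592 with an estimated correlation. Glycolysis genes lay higher in HT4 (0.24) and TF1 (0.18), with camera and Benjamini-Hochberg adjusted p = 0.00196 and 0.00497, and adjusted p = 0.959 and adjusted p = 0.989 with an estimated correlation.

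Further lists were called in fewer comparisons or with 1 called gene. Galactose regulon genes were not called against FHT-WT1 in any strain, and lay lower than in the null strain in TF1 (-0.17) and DT1 (-0.14), with camera in limma and Benjamini-Hochberg adjusted p = 0.00133 and 0.0187, and adjusted p = 0.95 and adjusted p = 0.989 with an estimated correlation. TFIID subunits were called above the null strain in all 4 construct strains (medians 0.11, 0.07, 0.12 and 0.07), with TAF1 the 1 member called, and this rested on TAF1. Their camera Benjamini-Hochberg adjusted p was 0.00135, 0.000122, 0.00077 and 0.00269, with an adjusted p = 0.95 or more with an estimated correlation, and in DT1 the call was lost on centred arrays (adjusted p = 0.0686). Without TAF1, the other 14 subunits were not called in any of the 4 (camera, Benjamini-Hochberg adjusted p = 0.518, 0.351, 0.387 and 0.412). Auxotrophic marker genes were called in the 4 construct strains against FHT-WT1 (medians 0.23, 0.33, 0.30 and 0.03), led by MET17, with adjusted p = 0.417 or more with an estimated correlation. In PB1 this call was lost on centred arrays (camera, Benjamini-Hochberg adjusted p = 0.302). Against the null strain the markers were called in all 4 construct strains as deposited, and on centred arrays no longer in HT4 (adjusted p = 0.0635 by camera in limma with Benjamini-Hochberg) or PB1 (adjusted p = 0.721). These calls were lost, with adjusted p = 0.438, adjusted p = 0.417, adjusted p = 0.473 and adjusted p = 0.959 with an estimated correlation in DT1, TF1, HT4 and PB1. In PB1 against the null strain the median of these markers was -0.06 while the mean, carried by MET17, was 0.49. General stress genes lay at -0.17 in DT1 and 0.14 in HT4 against the null strain (camera, Benjamini-Hochberg adjusted p = 0.000312 and 0.0156; adjusted p = 0.989 with an estimated correlation for each). Ribosome biogenesis genes lay at 0.19 in DT1 against the null strain, ergosterol genes at 0.10 in DT1 and 0.11 in HT4, and cyclins at 0.16 and RNA polymerase II genes at 0.11 in PB1 (camera, Benjamini-Hochberg adjusted p between 0.000513 and 0.0475; adjusted p = 0.989 with an estimated correlation for each). SAGA subunits, mitochondrial ribosomal proteins and mating type a genes were not called in any of the 10 comparisons by camera in limma. Of the 190 list tests 76 were called with the preset correlation, 76 on centred arrays, and 0 with an estimated correlation or by fry.

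The changes of the construct strains were compared with those of the null strain. Across 5535 genes, which are not independent replicates, the changes against FHT-WT1 correlated with those of the null strain at r = 0.650 in DT1, 0.745 in TF1, 0.734 in HT4 and 0.646 in PB1. Groups that share the FHT-WT1 arrays and do not change gave a simulated r of 0.499, with 0.55 the highest of 100 draws. The covariance was 0.047, 0.058, 0.069 and 0.057, against 0.014 simulated, which leaves 0.033, 0.045, 0.055 and 0.043 beyond the simulated value. The simulated noise was independent between genes, so it cannot show how far r and covariance vary in unchanged groups whose genes vary together. Whether r and covariance exceed those of such groups is therefore not decided. Without null strain array 1, r was 0.437 in DT1, 0.529 in TF1, 0.593 in HT4 and 0.573 in PB1, and without null strain array 2 it was 0.497 in PB1. With 1 null strain array the simulated r was 0.405, with 0.465 the highest of 100 draws, and DT1 then lay below that highest value. The simulation held no effect of dye orientation, which stays in the profile of a lone array. It therefore cannot decide whether r in DT1 exceeds that of unchanged groups. With FHT-WT1 not subtracted, the ratios to the reference correlated with those of the null strain at 0.744, 0.822, 0.809 and 0.745. These ratios share the reference strain, and no value for unchanged groups was simulated for them, so they are not read as shared changes. Among the construct strains, r was highest between DT1 and TF1 (0.859) and lowest between DT1 and PB1 (0.622). The spread of the changes beyond array noise was 0.194 in DT1, 0.220 in TF1, 0.283 in HT4, 0.262 in PB1 and 0.231 in the null strain (SD, log2).

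Called genes were also shared with the null strain. After centring, 30 of the 39 genes lower in DT1 were also lower in the null strain, as were 108 of 145 in TF1, 171 of 377 in HT4 and 113 of 257 in PB1, where independent lists would share 1.61, 5.97, 15.5 and 10.6. Lists of the same lengths, ranked in 50 simulations of unchanged groups that share the FHT-WT1 arrays, had 17, 45.5, 83 and 66.3 genes in common on average and 25, 59, 107 and 84 at most. Genes higher in both numbered 6 of 11, 30 of 61, 60 of 271 and 42 of 150, where independent lists would share 0.21, 1.16, 5.14 and 2.85. The simulated averages were 4.7, 16.7, 39.5 and 28.6 and the highest 8, 25, 53 and 39, so the 6 shared with DT1 lay within the simulated range. As deposited, the genes higher in both numbered 3, 6, 9 and 16 in DT1, TF1, HT4 and PB1 (simulated at most 5, 7, 13 and 14) and those lower in both 5, 5, 6 and 4 (simulated at most 5, 4, 7 and 5), so the genes lower in TF1 and those higher in PB1 alone exceeded the simulated range. Part of the excess over independent lists may come from the shared controls. The simulated lists leave out real changes and noise shared between genes, so neither excess is read as a shared effect. As deposited, 5 genes were called the same way in all 5 strains against FHT-WT1: MEP2 and DUR3 higher, and MF(ALPHA)1, ECM15 and PUS5 lower, of which ECM15 and PUS5 were singled out after their values were seen. PUS5 rested on a single control array, as it lay at 2.04 on FHT-WT1 array 2 and at -0.125 on FHT-WT1 array 1. After centring there were 26, with MEP2, DUR3 and BDH2 higher and 23 lower, including ECM15 and DFP4 but not MF(ALPHA)1 or PUS5. In lists of the same lengths from 50 simulations of unchanged groups with the shared arrays, at most 2 higher and 2 lower genes were common to all 5 strains as deposited, and at most 5 higher and 13 lower after centring. The 2 genes higher as deposited and the 3 higher after centring thus lay within the simulated range. The simulated lists had fixed lengths whatever the size of their changes, so these counts cannot decide whether MEP2 and DUR3 rose. On the arrays of the 5 strains MEP2 lay at 0.86 to 2.47 and DUR3 at 0.85 to 2.23. On those of FHT-WT1 and the homotypic pair they lay at 0.09 to 0.5 and 0.13 to 0.44.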

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

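Each construct strain differed from the null strain in a direct test, which is what brought the following results here, and those comparisons were planned, while the tests of explanations for MET17, BUD6 and EST2 were chosen only after the results were seen. With limma, the genes called against the null strain numbered 41 in DT1, 9 in TF1, 10 in HT4 and 26 in PB1. Averaged over the construct strains, the change over the null strain was 4.82 for MET17, 2.80 for TAF1, 1.59 for BUD6 and 0.82 for YDR222W. It was -1.27 for PAL1, -0.98 for JEN1, -0.94 for KAP104, -0.88 for YHB1, -0.81 for PHO89 and -0.60 for YCR101C. Without null strain array 2 the value was -0.12 for PAL1, -0.25 for KAP104 and 0.076 for YDR222W, and without null strain array 1 it was -0.48 for PHO89 and -0.40 for YCR101C. The strains differed at YCR101C, with -1.43 in PB1, -0.90 in DT1, -0.16 in HT4 and 0.087 in TF1. After centring, MET17, TAF1 and BUD6 were called in all 4 strains, PHO89, YCR101C and YDR222W in 1, and PAL1, JEN1, KAP104 and YHB1 in 0 by limma.

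MET17 was higher in the 4 construct strains and not in FHT-WT1 or the null strain, with a mean log2 ratio of 4.80 over the 8 construct arrays (SD 0.43). Induction of the sulfur amino acid genes as a group is argued against: the median change of 14 other genes of that pathway was -0.19 (SD 0.099), and the highest was 0.039. An effect of any TAF1 construct would also reach FHT-WT1, the wild type construct strain, where MET17 lay at 0.137 and -0.347. The lowest construct array lay 3.73 above the highest of the other arrays. A difference in genotype at MET17 and an effect particular to the TAF1 constructs of these 4 strains would both give this. These cannot be told apart here, because both concern the same 4 strains and the strain genotypes are not given in the sources used here. A strain background that differs between the construct strains and their controls may also contribute to other genes called in these comparisons.

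BUD6 rose in the same strains as MET17, and its chromosomal neighbour EST2, chosen after its values were seen, rose against FHT-WT1 in TF1 (0.96), HT4 (0.88) and PB1 (1.15) but was not called in DT1 (0.58) by limma, and against the null strain was called in PB1 (1.10) but not in DT1 (0.53), TF1 (0.92) or HT4 (0.83) as deposited. A gain of the stretch from MET17 to BUD6 is argued against, as the median change of the 12 genes between MET17 and EST2 was -0.043 (SD 0.179, highest 0.432). Material of MET17 in features with neighbouring numbers could reach BUD6 (feature 3357, beside 3356 for MET17), which stays open with RPS30A just before MET17 at -0.16 and ARV1 just after BUD6 at 0.41, but it would not reach EST2 (feature 2475), whose mean change was 0.97 (SE 0.125). A difference in genotype at EST2 and BUD6 cannot be told apart from an effect particular to the constructs of DT1, TF1, HT4 and PB1. The lowest construct array lay -0.022 from the highest other array for EST2, within the residual SD of 0.256, and 0.556 above it for BUD6. An effect of these TAF1 constructs on both genes was not tested and stays open.

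Lists that differed from the null strain with camera and the preset correlation are given as medians relative to all genes, and none passed with an estimated correlation. The TFIID calls rested on TAF1, without which the other 14 subunits were not called in any of the 4 strains (camera in limma, Benjamini-Hochberg adjusted p = 0.351 or more). In DT1 the lists were TFIID subunits (0.11), cytosolic ribosomal proteins (0.15), ribosome biogenesis (0.19), general stress (-0.17), galactose regulon (-0.14), respiratory chain (-0.34), ergosterol (0.10) and auxotrophic markers (0.12). In TF1 they were TFIID subunits (0.070), heat shock chaperones (0.16), galactose regulon (-0.17), glycolysis (0.18), respiratory chain (-0.38), alpha-specific genes (-0.34) and auxotrophic markers (0.18). In HT4 they were TFIID subunits (0.12), cytosolic ribosomal proteins (-0.11), heat shock chaperones (0.27), general stress (0.14), glycolysis (0.24), respiratory chain (-0.23), ergosterol (0.11) and auxotrophic markers (0.14). In PB1 they were TFIID subunits (0.073), RNA polymerase II and general factors (0.11), cytosolic ribosomal proteins (0.17), heat shock chaperones (0.60), cyclins (0.16), amino acid biosynthesis (-0.40), alpha-specific genes (-0.60) and auxotrophic markers (-0.059). The markers were called as higher in PB1, with a mean of 0.49 carried by MET17, opposite in sign to their median, and this call was lost on centred arrays (camera in limma, Benjamini-Hochberg adjusted p = 0.721).

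Features without a gene name were outside the comparisons, and some of them were called. What these features hold is not known, and whether their calls reflect signal was not tested. Of 1048 such features on all arrays, limma called 4 in DT1 (0 higher and 4 lower), 2 in TF1 (1 and 1), 10 in HT4 (2 and 8) and 9 in PB1 (7 and 2) against FHT-WT1. Against the null strain it called 8 in DT1 (0 and 8), 1 in TF1 (0 and 1) and 1 in HT4 (0 and 1). The count of called unnamed features was not repeated on centred arrays. Single outlying arrays were not looked for within groups of 2, and the effect of leaving out each array is given with the processing.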

How the results depend on the processing

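Alternatives on centred arrays and with unnamed features were added after seeing the data, and the others were planned. Every count of called genes below moved by more than 1.5 times under at least 1 alternative, and the cause was not tested except where it is named. Counts follow the order DT1, TF1, HT4, PB1 and null strain against FHT-WT1, then DT1, TF1, HT4 and PB1 against the null strain. As deposited they were 49, 29, 341, 107 and 38, then 41, 9, 10 and 26. With each array centred on its median they were 50, 206, 648, 407 and 333, then 4, 3, 28 and 65. With arrays also scaled to 1 median absolute deviation they were 3, 1, 23, 14 and 1, then 3, 3, 2 and 3. That scaling by construction enlarges arrays of low spread, and it gave 8 for FHT-WT1 against the homotypic pair. Without the orientation term they were 2, 3, 17, 10 and 1, then 2, 3, 2 and 4. With arrays of only the 2 groups compared they were 84, 210, 916, 29 and 2, then 5, 16, 2 and 2. With array weights they were 1303, 95, 1700, 159 and 1, then 2, 2, 2 and 2, and 947 for FHT-WT1 against the homotypic pair. With unnamed features included they were 7, 5, 62, 30 and 1, then 14, 4, 3 and 4. With the homotypic arrays as control they were 1151, 458, 1927, 465 and 425, and with homotypic array 2 taken as not turned 69, 62, 317, 80 and 33. A robust prior gave 49 for TF1 against FHT-WT1, 26 for HT4 against the null strain and 7 for FHT-WT1 against the homotypic pair. FHT-WT1 against a log2 ratio of 0 gave 4.

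On centred arrays, leaving out the orientation term gave 4, 6, 98, 55 and 3 against FHT-WT1, and 2, 4 and 6 for DT1, HT4 and PB1 against the null strain. Arrays of only 2 groups gave 1, 744, 333, 1 and 111, then 63 for DT1 and 33 for PB1 against the null strain, and 67 for FHT-WT1 against the homotypic pair. Array weights gave 95 for DT1, 392 for TF1 and 3 for the null strain against FHT-WT1, and 12 for HT4 and 12 for PB1 against the null strain. The homotypic arrays as control gave 462, 859, 1367, 1156 and 961. A minimum of 1.5-fold gave 131, 334, 239 and 173 for TF1, HT4, PB1 and the null strain.

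With 1 array left out in turn, where the lone array of a group is assumed to vary like the others, the counts as deposited ranged from 11 to 367, 10 to 140, 36 to 1200, 36 to 359 and 16 to 877, then 10 to 2905, 4 to 258, 7 to 3693 and 13 to 583. FHT-WT1 against the homotypic pair ranged from 0 to 15, and from 0 to 8 on centred arrays. On centred arrays the ranges were 1 to 80, 3 to 287, 159 to 801, 103 to 592 and 1 to 709, then 2 to 146, 2 to 53, 2 to 62 and 15 to 82. The median log2 ratio ranged from 0.043 to 0.068 in FHT-WT1, -0.108 to -0.102 in DT1, -0.038 to 0.208 in TF1, -0.172 to -0.129 in HT4, 0.032 to 0.21 in PB1, -0.184 to 0.412 in the null strain and 0.244 to 0.301 in the homotypic pair (0.029 with array 2 not turned). With the mode in its place it was 0.089 in FHT-WT1, -0.087 in DT1 and -0.101 in HT4. The correlation with the null strain ranged from 0.437 to 0.752 in DT1, 0.529 to 0.809 in TF1, 0.593 to 0.788 in HT4 and 0.497 to 0.718 in PB1. With FHT-WT1 not subtracted it was 0.809 in HT4 and 0.745 in PB1.

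Of 190 list tests, 0 were called with an estimated correlation, 0 by fry and 0 on centred arrays with an estimated correlation. By fry, which does not compare a list with other genes and so follows the shift of the array, the direction reversed for heat shock chaperones (0.1234), general stress (0.1266) and amino acid biosynthesis (0.0792) in FHT-WT1 against the homotypic pair. It also reversed for cytosolic ribosomal proteins (0.1472), ribosome biogenesis (0.1854) and ergosterol (0.0991) in DT1 against the null strain. In HT4 against the null strain it reversed for TFIID subunits (0.1234), general stress (0.1366), glycolysis (0.241) and ergosterol (0.1144). TAF1 against FHT-WT1, not called, changed sign in TF1 (0.043) and PB1 (0.053) with arrays scaled to 1 median absolute deviation. The promoter test was not run, and centring cannot change a correlation across genes. Signal over background is not given in the sources used here, so the limit it sets is unknown. Values at log2 ratios of small whole numbers, as in the unnamed features, also occurred in named genes. YIL055C lay at 2.3219 on DT1 array 2 and AIM19 at 2.3219 on FHT-WT1 array 2. GTA1 lay at 2.585 on PB1 array 2, PAL1 at 1.585 and SSB1 at -1.2224 on HT4 array 2. Their signal may be low, which was not tested, so the size of the changes given for these genes is uncertain.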

Other observations

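The lists and tests in this part were chosen only after the results were seen. The list of nitrogen catabolite repressed genes holds MEP2 and DUR3, and the tricarboxylic acid cycle list holds ACO1. These were already among the called rises. The lists were not tested without these genes, so their p-values partly retest them. Genes under nitrogen catabolite repression, which cells express when good nitrogen sources are scarce, lay higher against FHT-WT1. The median of 24 such genes relative to all genes was 0.41 in DT1 (22 above), 0.53 in TF1 (23 above), 0.49 in HT4 (24 above) and 0.34 in the null strain (22 above), with Benjamini-Hochberg adjusted p from camera in limma of 4.23e-17, 1.23e-19, 1.23e-13 and 2.5e-12, and adjusted p = 0.379 with an estimated correlation for each. In PB1 it was 0.18 (adjusted p = 0.00165 with camera in limma and Benjamini-Hochberg; adjusted p = 0.712 with an estimated correlation), and PB1 lay -0.25 below the null strain (adjusted p = 4.38e-05 with camera in limma and Benjamini-Hochberg; adjusted p = 0.617 with an estimated correlation). Genes called against FHT-WT1 numbered 2, 5, 3, 2 and 4 in DT1, TF1, HT4, PB1 and the null strain, and 2, 6, 8, 2 and 4 after centring. In DT1 the 2 were MEP2 and DUR3. With homotypic array 2 taken as turned, the list lay higher in FHT-WT1 than in the homotypic pair (21 of 24 above all genes). The median there was 0.12 (camera in limma, Benjamini-Hochberg adjusted p = 0.000297, and adjusted p = 0.662 with an estimated correlation).

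Tricarboxylic acid cycle genes were highest in the null strain (median of 17 genes 0.61, camera in limma, Benjamini-Hochberg adjusted p = 1.2e-13) and PB1 (0.52, adjusted p = 7.48e-10), followed by HT4 (0.35, adjusted p = 2.2e-08), with adjusted p = 0.379 with an estimated correlation for each. Set directly against the null strain, these genes were not called in PB1 (-0.086) or HT4 (-0.013), with camera in limma and Benjamini-Hochberg adjusted p = 0.404 and 0.17. They lay below the null strain in DT1 (-0.35) and TF1 (-0.25; camera in limma, Benjamini-Hochberg adjusted p = 2.73e-08 and 4.98e-09; adjusted p = 0.379 with an estimated correlation for each), and 4 genes fell in DT1 as deposited and 0 after centring. BNA1, a gene of NAD synthesis, fell by 1.04 in DT1, 0.92 in TF1, 1.08 in HT4 and 1.09 in PB1 against FHT-WT1, and lay at -0.80 in the null strain (limma, Benjamini-Hochberg adjusted p = 0.0861), where it fell after centring (-0.86, adjusted p = 0.0182). The list of 12 NAD genes had a median of -0.20 in PB1, -0.17 in DT1 and -0.10 in TF1 (camera in limma, Benjamini-Hochberg adjusted p = 0.00326, 0.0129 and 0.0216). With an estimated correlation these were lost (adjusted p = 0.613, adjusted p = 0.662 and adjusted p = 0.68 with an estimated correlation). The NAD list holds BNA1, its 1 called member in DT1 and TF1 as deposited, and was not tested without it. The 14 other sulfur amino acid genes lay at 0.38 in FHT-WT1 against the homotypic pair (camera in limma, Benjamini-Hochberg adjusted p = 6.62e-15; adjusted p = 0.379 with an estimated correlation). They lay at -0.32 in DT1 against FHT-WT1 (camera in limma, Benjamini-Hochberg adjusted p = 0.000643; adjusted p = 0.511 with an estimated correlation). Against the null strain they lay at -0.41 in DT1, -0.23 in HT4 and -0.28 in PB1 (camera in limma, Benjamini-Hochberg adjusted p = 4.82e-10, 0.00174 and 6.56e-05), with adjusted p = 0.379, adjusted p = 0.565 and adjusted p = 0.384 with an estimated correlation.

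Arrays of 1 dye orientation resembled each other more than the 2 arrays of a strain. Dye bias or another effect of the hybridisation set stays open as an explanation: the orientation coefficient fitted on the 12 strain arrays correlated across 5535 genes with the difference of the homotypic arrays at r = 0.594. This took homotypic array 2 as turned like the other second arrays, which is not stated; taken as not turned, r was -0.155, which would speak against the explanation. HSP26, chosen after its values were seen, had a coefficient of 0.54. Dye and hybridisation set were not separated, and no biological explanation was tested because both arrays of a homotypic pair hold the same strain. By its title number, array 2 of FHT-WT1 stands with homotypic array 2, apart from array 2 of the other strains. The labels do not explain these numbers. Homotypic array 2 correlated with array 2 of FHT-WT1 at r = 0.272, and with array 2 of the other strains at -0.0309 to 0.0894. Whether a difference in set adds to the changes against FHT-WT1 was not tested, and it cannot be excluded.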
